A study of Mus musculus with 2 samples.

How the data were processed

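H3K4me1 chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on the facial prominences of B6NCrl mouse embryos at embryonic day 11.5. H3K4me1 is histone H3 carrying 1 methyl group on lysine 4, a mark of enhancers and of the flanks of active promoters. The facial prominences are the swellings of the embryonic head that grow and fuse into the jaws, nose and lips. Per the labels, replicate 1 was a pool of tissue from 109 embryos and replicate 2 a pool from 88 embryos, each of both sexes. The labels list technical replicates 1 and 2 for replicate 2, without saying whether these were libraries or sequencing runs. Both replicates form 1 group, and the labels give no second condition, so the comparisons made were replicate against replicate and peaks against the genome annotation. Each replicate is 1 pool of embryos, so values are given per replicate and no p-value was computed across peaks or genes.

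The deposited data were 4 peak lists in narrowPeak layout on mouse build mm10, described per the deposited text files that came with them. There was 1 list for each replicate, 1 list called on the filtered alignments of both replicates pooled, and 1 list of replicated peaks made from the other 3. Each call was made against control alignments. The peak caller, its thresholds, the aligner and the rule for keeping a replicated peak are not given in the sources used here. The deposited strength of a peak was read as the ratio (fold enrichment) of ChIP over control, from its values and the narrowPeak layout, since no label or text file states its meaning. The deposited lists also give a -log10 p and a -log10 q per peak from the authors' caller, where a -log10 q of 0 stands for q = 1. These strengths are the authors' values and were used here to rank, filter or describe peaks within a list, to set overlapping peaks of the replicates side by side, and in the test of X copy number. Read counts were not used here, so the depth of each library is unknown, and intervals given for shares of peaks are 95% Wilson intervals that cover counting error only. The lowest -log10 p was 2.00, so the lists hold weak as well as strong peaks, and the number of peaks depends on depth and on that threshold.

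Peaks on the 21 assembled chromosomes were kept, which left out 2 peaks of each replicate list, 2 of the pooled list and 1 of the replicated list. Chromosome lengths and gene positions came from the GRCm38 reference sequence and the GENCODE M21 annotation, the same assembly as mm10, and every peak lay within the chromosome lengths. Coordinates are 1-based. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

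Peaks of 2 lists were counted as overlapping from 1 bp of shared sequence, and the Jaccard index was the number of bases covered by both lists divided by that covered by either. Chance overlap came from 100 rotations, in which the peaks of each chromosome were shifted by 1 random distance. Peak midpoints were assigned to promoters (within 1 kb of the transcription start site (TSS) of a protein-coding gene), then exons, introns and intergenic sequence, and each share was divided by its mean over 100 rotations. The share of 21938 protein-coding TSSs covered by a peak was taken every 100 bp from 5 kb upstream to 5 kb downstream, and coverage within 100 bp of the TSS was divided by coverage 1 to 2 kb from it. Promoters were split at the median of their CpG observed to expected ratio, 0.553.

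The covered share of the 100 kb around each TSS (50 kb on each side) was computed for 21911 protein-coding gene symbols. For 16 gene lists fixed before the data were examined, the median share was ranked among 10000 random lists matched member by member on the number of TSSs in the window and on gene length, in 5 bins each. A list was said to stand apart when its percentile was at least 97.5 or at most 2.5 in the replicated list and in both replicates. Random lists draw genes one by one, so the percentile of lists whose genes share windows, such as Hox clusters, receptor clusters and Dlx genes, understates chance spread. To set the replicates side by side, replicate 1 was reduced to its 18093 strongest peaks by fold enrichment, the number in replicate 2, and values at that equal number are given as mean ± SD (n = 2). The difference between replicates in each list was the median log2 ratio of the covered shares, with 1 percentage point added to each.

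Named genes followed a rule fixed before the data were examined. From each list, the 4 members with the highest covered share in the replicated list and up to 4 members, in alphabetical order, with no replicated peak in the window could be named. To these came the 15 genes with the highest share of all, skipping any TSS within 100 kb of one taken. The 10 replicated peaks of highest enrichment, the 10 widest, and the 10 peaks of each replicate with the highest enrichment and no overlap in the other were also open to naming.

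The computations were tested on simulated data. Peaks placed on replicate 1 at shares of 10.1%, 50.4% and 90.1% were found at those shares, and 10.2% and 40.4% of peaks placed at promoters were found there. The other simulated peaks had been cleared of any that met the rule, so this agreement was built in and checks the counting alone. Of 20 lists with 3 planted peaks per gene, 100% stood above their random lists, and of 200 randomly drawn lists 0% stood apart in all 3 peak lists, among 21911 genes. Alternatives covered the overlap rule, stricter -log10 p and -log10 q thresholds, the promoter definition, the window, the matching and each replicate alone, and those chosen after seeing the data are named with their effect in the closing section.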

Results

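H3K4me1 was mapped in the facial prominence of mouse embryos at embryonic day 11.5, in 2 separate pools of 109 and 88 embryos (replicates 1 and 2). Replicate 1 gave 55334 peaks and replicate 2 gave 18095, and 36172 were called on both pools together. The deposited replicated list held 17365 peaks. On the assembled chromosomes, peaks covered 14.9 Mb in replicate 1, 4.56 Mb in replicate 2 and 6.39 Mb in the replicated list. Called peaks were narrow, with a median width of 221 bp in replicate 1, 217 bp in replicate 2 and 313 bp in the replicated list. The lower quartile of width was 182 bp in replicate 1 and 184 bp in replicate 2, close to the minima of 170 and 175 bp. These are widths of called intervals from an unnamed caller, so they do not measure how wide a marked region is. Their median enrichment over control was 3.51 in replicate 1 and 3.35 in replicate 2. At a q of 0.05, 39955 peaks of replicate 1 (72.2%) and 0 peaks of replicate 2 passed, and 78.3% of replicate 2 peaks had a -log10 q of 0. Of the pooled list 7156 peaks (19.8%) passed. Of the replicated list, the main set for the results on location and genes, 6308 (36.3%) passed. The sequencing depth behind these lists is unknown.

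The first comparison asked how far the maps of the 2 embryo pools coincide. The 10 peaks of highest enrichment in the replicated list, which was made from both replicates, each overlapped a peak in each replicate. The strongest lay at chromosome 11, 98964361 to 98965888, in an intron of Rara, the gene of a retinoic acid receptor. Its enrichment was 7.42 in the replicated list, 9.55 in replicate 1 and 4.06 in replicate 2. Intronic peaks of Kirrel and Gse1 (6.99 each) and of Ncor2 (6.97), which encodes a nuclear receptor corepressor, followed closely. Of the others, 1 more lay in an intron of Gse1, and 1 each in introns of Atoh8, Sema3f, Ntn1 and Sdc3. An intronic peak of Bop1 at chromosome 15, 76464820 to 76466559, lay 8.24 kb from the TSS of Scx, a transcription factor of tendon progenitors.

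Over all peaks the lists coincided far beyond chance but only in part. Of replicate 2 peaks, 53.3% (interval 52.6 to 54.0%) overlapped a replicate 1 peak, against 1.23% on average and at most 1.61% in the rotations. Of replicate 1 peaks, 17.5% (17.2 to 17.8%) overlapped a replicate 2 peak, against 0.406%. The Jaccard index of covered bases was 0.109, against 0.00157 in the rotations. Overlap depended on strength, and among the strongest 10% it reached 41.5% of replicate 1 peaks and 77.6% of replicate 2 peaks, against 12% and 45.4% among the weakest 10%. Across the 9695 replicate 1 peaks with a partner, enrichment in both replicates was weakly related, with a Spearman rho of 0.134 and a Pearson r of 0.148 on the log2 scale. These coefficients are across peaks, which are not independent replicates. Only regions called in both lists enter, each with its strongest replicate 2 partner, and the range of enrichment is narrow. Its quartiles over all peaks were 3.18 and 4.02 in replicate 1 and 2.99 and 3.74 in replicate 2. The coefficients therefore do not measure agreement over the whole range of signal. At the same number of strongest peaks, 27.6% of replicate 1 and 29.6% of replicate 2 peaks overlapped.

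**Figure D1:**
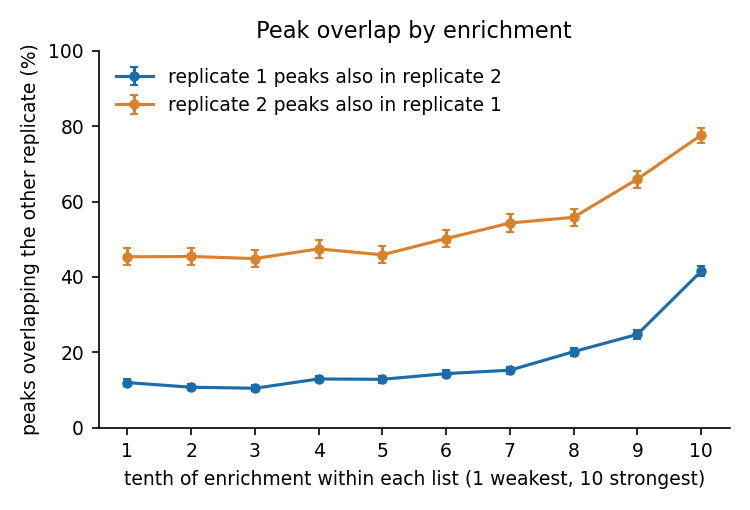
Share of peaks (%) overlapping the other replicate by at least 1 bp, by enrichment within each list, in 10 groups of equal size, with 95% Wilson intervals as bars. The share was 45.4% in the weakest group of replicate 2 and reached 77.6% in the strongest, and it went from 12% to 41.5% in replicate 1.

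The replicated list was a subset of the pooled list, with all 17364 of its peaks on assembled chromosomes present there at the same interval (48.0% of pooled peaks). A replicate 1 peak overlapped 91.5% of replicated peaks and a replicate 2 peak 57.2%. Both replicates had a peak at 8930 of them (51.4%), replicate 1 alone at 6964, replicate 2 alone at 1004 and neither at 466. Replicated peaks present in both had a median enrichment of 3.75, against 3.42 for the rest. The word replicated therefore names the deposited list here, and not a peak in both replicates.

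The next comparison asked where in the genome the mark lies. Promoters and exons held more peaks than random placement and intergenic sequence fewer, while most peaks in number lay in introns and intergenic sequence. In the replicated list, 12.7% of peaks lay at promoters, 7.54 times the share of the rotations. Exons held 9.30% (2.63 times), introns 49.7% (1.34 times) and intergenic sequence 28.2% (0.489 times). The replicates gave 6.84 ± 0.161 times at promoters (SD, n = 2), 2.32 ± 0.158 in exons, 1.35 ± 0.00902 in introns and 0.528 ± 0.0221 in intergenic sequence. No rotation of the replicated list reached its promoter share, the highest being 2.02%. The median distance to a protein-coding TSS was 18.1 kb, and 59.5% of replicated peaks lay more than 10 kb away.

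Around the TSS, CpG-rich and CpG-poor promoters carried the mark in different places. CpG-rich promoters, which include those of most broadly expressed genes, were covered less at the TSS itself than on either side of it. In the replicated list 4.90% of them were covered 1000 bp downstream and 2.01% at 900 bp upstream, against 1.51% at the TSS. CpG-poor promoters were covered most at 100 bp downstream (2.10%). The ratio of coverage at the TSS to that of the flanks was 0.633 for CpG-rich promoters, with 0.660 in replicate 1 and 0.590 in replicate 2. For CpG-poor promoters it was 3.02, with 2.90 in replicate 1 and 2.69 in replicate 2. The gap between the 2 promoter classes exceeded the gap between replicates in either class.

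**Figure D2:**
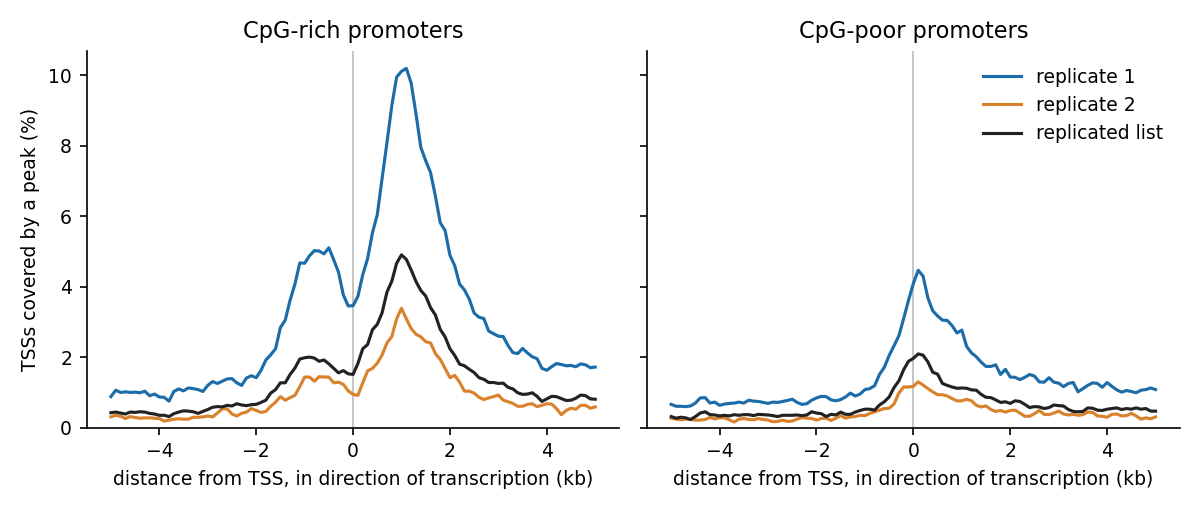
Share of protein-coding TSSs (%) covered by a peak at each distance from the TSS (kb, in the direction of transcription), for 10969 CpG-rich and 10969 CpG-poor promoters, with 1 line for each replicate and for the replicated list. The lines of CpG-rich promoters dip at the TSS, to 3.46% in replicate 1, and peak about 1 kb downstream, at 10.2% in replicate 1, whereas those of CpG-poor promoters peak beside the TSS.

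Chromosomes differed in peak density, and the X and Y stood apart from the autosomes. The Y held 1 peak in each replicate and 0 in the replicated list. The X held 137 peaks in replicate 1, 22 in replicate 2 and 6 in the replicated list, while it makes up 6.18% of the genome. This amounted to 0.838 peaks per Mb in replicate 1, against 23.0 on the autosomes, a ratio of 0.0364. The ratio was 0.0178 in replicate 2 and 0.00507 in the replicated list, with an exact Poisson interval of 0.00186 to 0.0110. Among autosomes, chromosome 11 was densest and chromosome 3 sparsest in each list, with 15 and 3.88 replicated peaks per Mb. Chromosome 11 also had the highest GC content of the autosomes (43.8%) and chromosome 3 the lowest (40.5%), and these densities were not corrected for it. X-linked genes such as Gata1 and Alas2 of the red cell lineage and Dcx of migrating neurons had no replicated peak in their windows. Tbx22, an X-linked transcription factor gene of palate development, had none either (0%; named after its value was seen).

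**Figure D3:**
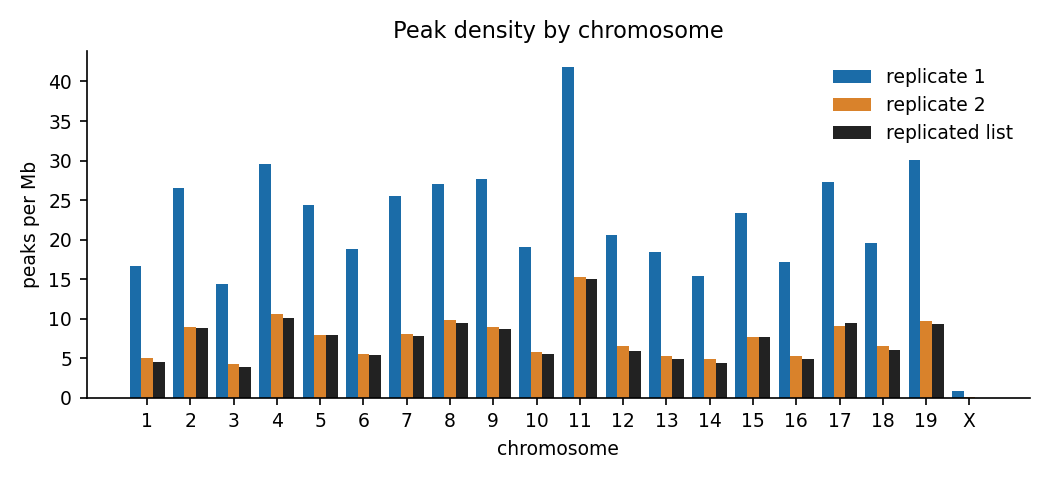
Peaks per Mb of assembled sequence without gaps on each autosome and the X, with 1 bar for each replicate and for the replicated list. Chromosome 11 is the highest in each list (41.8 peaks per Mb in replicate 1), and the X lies near 0 (0.838 in replicate 1).

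The next comparison asked whether peaks gather near genes of facial development. The transcription factor genes of facial mesenchyme, the cell population that builds the facial skeleton and connective tissue, were surrounded by peaks. Of 31 such genes, 24 had a replicated peak within 50 kb of the TSS, and their median window was 1.00% covered (replicate 1 2.66%, replicate 2 0.881%). This lay at the 100th percentile of 10000 matched random lists in the replicated list and in both replicates. The highest share was at Prrx2, a homeobox gene of craniofacial mesenchyme at chromosome 2, 30834972 to 30881251, with 26 replicated peaks covering 13.7% of the window. At equal peak number Prrx2 had 8.89 ± 0.158% (SD, n = 2). Snai1, a regulator of epithelial to mesenchymal transition, had 7.86% (4.50 ± 2.51% at equal number), Pbx1 had 6.81% (4.50 ± 1.39%) and Foxc2 5.23% (2.43 ± 1.05%). Not every member was marked in the replicated list. Alx1, Prrx1, Runx2 and Shox2 had no replicated peak, although Prrx1 was covered at 1.46% in replicate 1 and 0.494% in replicate 2. Shox2 was covered at 0.170% and 0.903%. Alx1 and Runx2 had 0.231% and 0.31% in replicate 1 and 0% in replicate 2.

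Genes of jaw patterning and of facial signalling also stood above their random lists, at the 100th percentile in the replicated list and both replicates. In the jaw list, built on the endothelin and Dlx genes that set upper against lower jaw identity, 13 of 14 genes had a replicated peak. Dlx4 had 2.63% of its window covered, Dlx3 2.44%, Dlx1 2.13% and Barx1 1.62%. Dlx3 and Dlx4 are neighbours on chromosome 11 and share most of their windows. The 14 genes fall into 11 groups of windows, so some peaks count for more than 1 gene. Random lists drawn gene by gene then understate the chance spread of this list. Only Edn1, which encodes the endothelin ligand, had no peak in its window in the replicated list or in either replicate. In the signalling list 24 of 28 genes had a replicated peak, led by Fgfr1 (5.60%, 2.61 ± 0.0905% at equal peak number) and Axin2, a target of Wnt signalling (5.32%, 3.18 ± 0.140%). Bmp7 (5.26%) and the Hedgehog receptor gene Ptch1 (4.01%) followed. Fgf9, Gli3, Rspo2 and Tgfb2 had no replicated peak, although in replicate 1 they were covered at 0.206%, 1.39%, 0.366% and 0.647%. In replicate 2 Fgf9 had 0.503% and Tgfb2 0.315%, while Gli3 and Rspo2 had 0%.

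Facial epithelium and skeletal matrix genes stood above their random lists less firmly. Of 18 epithelial genes 13 had a replicated peak (median 0.587%, percentile 99.9), led by Grhl3, an epidermal regulator, with 2.71%, and by the keratin genes Krt18 (1.96%) and Krt8 (1.76%). Krt8 and Krt18 are neighbours on chromosome 15 and share most of their windows. Krt5, Krt14 and Perp, which mark stratified epithelium, had no peak in either replicate. Without peaks within 2.5 kb of a TSS the epithelial percentile was 49.3, from list and random medians that were both 0, with 90.8 in replicate 1. It was 93.3 when matched also on GC content of the window, and with matching on the promoter CpG ratio the call ended in replicate 2 (97.0). Of 17 skeletal genes 14 had a replicated peak (median 0.577%, percentile 99.7). Col2a1, the main collagen of cartilage, had 4.28%, Comp 3.34% and Sp7, a regulator of osteoblasts, 2.80%, while Col11a1 had no peak in either replicate. This call was lost in replicate 1 at equal peak number (percentile 94.4), and in replicate 1 it was also lost when matched on GC content of the window (87.7), without peaks within 2.5 kb of a TSS (97.3) and against random lists without receptor genes (96.8).

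Markers of other cell types that a facial dissection could hold gave a mixed picture. Neural genes (median 0.366%, percentile 99.8) and skeletal muscle genes (0.257%, 97.8) stood above their random lists. Neurog1, a regulator of cranial sensory neurons, had 3.0%, Emx2 1.97% and Olig2 1.44%. Tbx1, active in the muscle progenitors of the pharyngeal arches, had 7.08% and the muscle filament gene Des 6.50%, whereas Chrna1, Mef2c, Msc and Tnnt1 had no replicated peak. The neural percentile was 91.5 when random lists were matched also on the promoter CpG ratio. The muscle call depended on the setting. Its percentile was 96.6 with that matching, 53.4 when matched also on GC content of the window, 96.2 against random lists without receptor genes, and 49.7 with peaks in both replicates alone, where list and random medians were both 0. Without peaks within 2.5 kb of a TSS these medians were also both 0 in the replicated list (49.6), while the replicates lay at 97.4 and 99.7. Endothelial genes did not stand apart (0.370%, percentiles 96.6, 96.9 and 98.7 in the replicated list and replicates 1 and 2), although Fli1 (5.21%) and Eng (5.16%) ranked high. Blood genes did not stand apart either (0%, 21.8), with a replicated peak at 6 of 17 genes and none at Gypa or Ank1. Nfe2, a transcription factor of the red cell lineage, had 3.71%, and Klf1, another, had 1.90%.

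Among tissues outside the dissection, heart genes stood above their random lists (0.485%, percentile 98.9), led by Myh6 (1.69%), Gata6 (0.944%) and Tnnt2 (0.934%). This call depended on the setting too. The heart percentile was 95.1 with windows of 100 kb on each side, 46.3 when matched also on GC content of the window and 97.0 with peaks in both replicates alone. Without peaks within 2.5 kb of a TSS it was 48.8, from medians that were both 0, with 95.3 in replicate 1 and 97.2 in replicate 2. The call also ended with windows of 20 kb (75.4 in replicate 1) and against random lists without receptor genes (96.5 and 95.8 in replicates 1 and 2). Liver genes (0%, 32.4), gut, pancreas and kidney genes (0.298%, 94.1) and pluripotency and germ line genes (0%, 37.8) did not stand apart. Alb, Afp and Apob, typical of liver, had no replicated peak, nor had the insulin genes Ins1 and Ins2. Housekeeping genes did not stand apart (0.257%, 82.3), although Rplp0, which encodes a ribosomal protein, had 8.82%. The Hox clusters, which pattern the body behind the face, lay at percentile 86.0 in the replicated list (0.661%), 99.3 in replicate 1 and 82.4 in replicate 2, with the highest shares at Hoxd8 (3.01%), Hoxd3 and Hoxd4 (2.77% each). When matched also on window GC, the Hox percentile was 1.415 in the replicated list and in replicate 2, and 44.6 in replicate 1. With matching on promoter CpG ratio it was 22.5, with 83.3 in replicate 1 and 17.3 in replicate 2. The list stood apart in neither setting. Olfactory and vomeronasal receptor genes were the only list below its random lists, with a replicated peak at 27 of 1464 genes and percentiles of 0.140 in the replicated list and 0 in each replicate. This call was lost (percentile 50 in the replicated list, list and random medians both 0) with windows of 20 kb, without peaks within 2.5 kb of a TSS, with matching also on promoter CpG ratio or window GC, and with peaks in both replicates alone. Where both medians are 0 the percentile cannot tell the lists apart. In replicate 1 the receptor percentile stayed at 0 in the first 2 of these settings, and was 11.4 with CpG matching and 50 with GC matching. In all, 8 of the 16 lists stood above, 1 below and 7 did not stand apart.

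**Figure D4:**
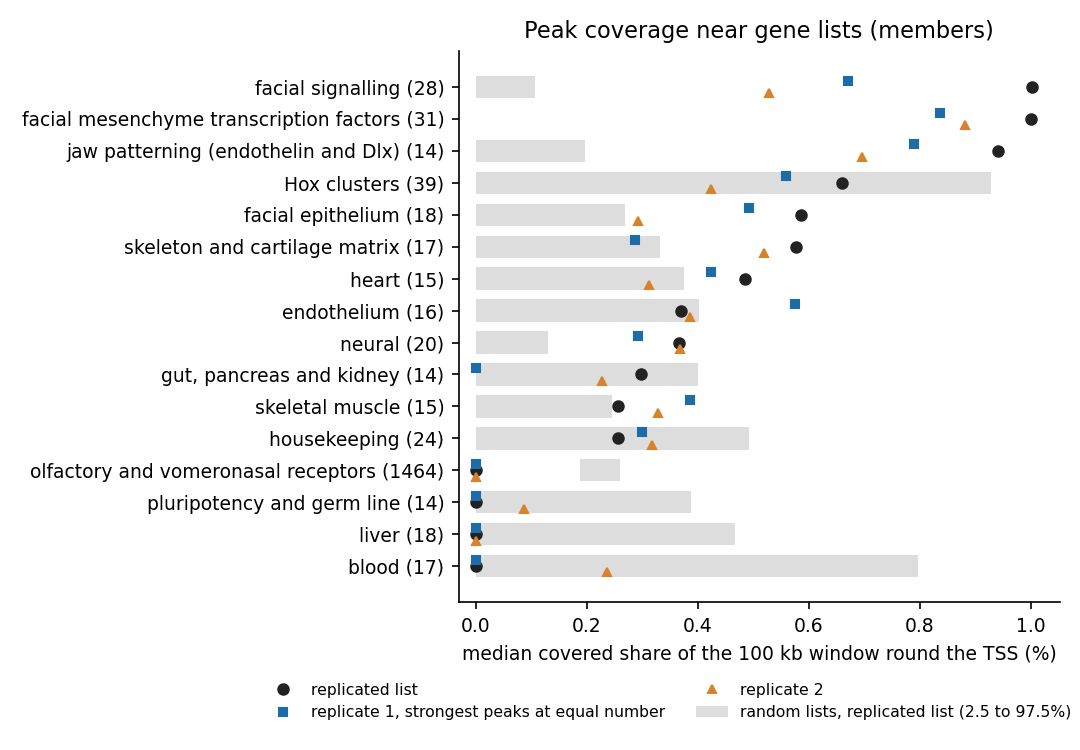
Median share (%) of the 100 kb window round the TSS covered by peaks for each gene list (number of members in parentheses), in the replicated list, in replicate 1 at equal peak number and in replicate 2, with grey bars for the middle 95% of medians of matched random lists in the replicated list. The 3 lists at the top that lie far from their bars are facial signalling (1.00%), facial mesenchyme (1.00%, its bar has no width because random medians were 0) and jaw patterning (0.942%).

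Over all genes, the most densely marked neighbourhood was that of Rara. Rara (chromosome 11, 98927818 to 98974942) had 38 replicated peaks covering 23.0% of its window, with 24.5% in replicate 1, 13.4% in replicate 2 and 15.9 ± 3.46% at equal peak number. Ahdc1 followed with 18.5% (15 ± 4.34%). Next came G430095P16Rik with 18.4%, whose TSS lies within the body of Nfix, and Bahcc1 with 17.2%. Asb6 (14.6%) is the neighbour of Prrx2 and shares its peaks. Cxxc5, a zinc finger gene linked to Wnt signalling, had 14.6%, Mrpl23 14.5%, Gse1 13.8%, Ncor2 13.5% and Foxp4, a forkhead factor gene, 12.3%. Over all 21911 genes the mean was 0.563% and 42.4% had a replicated peak in the window.

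The widest replicated peak spanned 2941 bp at chromosome 9, 57638352 to 57641292, in an intron of Csk, which encodes a kinase that restrains Src. The second widest, 2722 bp at chromosome 2, 157462284 to 157465005, lay in an intron of Src itself, 45.2 kb from its TSS. Introns of Gse1 on chromosome 8 held 3 of the 10 widest peaks, and the exonic peak at Scarf2 (2273 bp) was the only one of the 10 in an exon.

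The last comparison asked whether the 2 pools differ near markers of any tissue, at equal peak number. Equal number did not give equal coverage. Over all genes the mean window share was 0.515% in replicate 1 so reduced and 0.371% in replicate 2. A ratio above 0 therefore does not by itself mark a difference between the pools near genes of a tissue. The median log2 ratio of replicate 1 over replicate 2 was 0.31 for skeletal muscle genes (percentile 99.96), 0.11 for jaw patterning (98.8), 0.07 for epithelium (97.9), 0.05 for neural (99.0) and 0.04 for signalling genes (99.3). Skeletal matrix (0.05, 95.4), Hox (0.09, 84.3) and housekeeping genes (0.06, 92.3) stayed within the bounds. The median ratio was 0 for the facial mesenchyme list (49.8) and for the heart, blood, liver, gut, germ line and receptor lists. Endothelial genes had -0.02 (percentile 0.6), although their median share was 0.576% in replicate 1 and 0.386% in replicate 2. The neural medians also ran against their ratio, at 0.2935% in replicate 1 and 0.369% in replicate 2. Those of the muscle, jaw patterning, epithelium and signalling lists went with it. The size of these ratios depends on the 1 percentage point added to each share. With 0.1 point added, chosen after seeing the data, they were 0.37 for muscle, 0.35 for jaw patterning, 0.24 for Hox, 0.18 for epithelium, 0.17 for skeletal matrix and 0.10 for neural genes, with no change in which lists passed the bounds. With the strongest peaks taken by -log10 p, epithelium no longer passed (96.8). Most random medians were exactly 0, so small ratios reached extreme percentiles, and with all deposited peaks the endothelial percentile was 98.3.

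The strongest peaks seen in 1 replicate alone lay mostly in introns. In replicate 1 they included 2 intronic peaks of Rxra, which encodes a partner of retinoic acid receptors (enrichment 7.61 and 7.30), and intronic peaks of Bcl9l (7.62), Msi2 (7.30) and Wnt11 (7.0). In replicate 2 the highest lay in an intron of Tns1 (5.99), followed by an intronic peak of Igf2bp3 and promoter peaks nearest to Pamr1 and Fam92b (5.44 each) and an intronic peak of Tle3 (5.40). Each replicate is 1 pool, so no test separates a difference between pools from a missed call.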

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

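Facial mesenchyme, jaw patterning and signalling genes stood above their random lists under each of the 10 alternatives run for them, and promoter enrichment held under all but the 4-peak list below. None of those 10 alternatives filtered the replicated list by p or q. Chosen after seeing the data were the alternatives with -log10 p of at least 5, peaks in both replicates, window GC, random lists without receptor genes, 0.1 percentage point, the X with 1 replicate, and replicate 1 at equal peak number. Overlap of replicate 1 and replicate 2 peaks was 13.8% and 43.3% with 50% of either peak, 8.22% and 25.1% with 50% of both (rho 0.160), 27.6% and 29.6% at equal number (Jaccard 0.124), and 3.2% and 64.3% at -log10 p of 5 (Jaccard 0.0286, 25592 against 1209 peaks). A -log10 q of 2 or 5 left replicate 2 with 0 peaks, so those overlaps were not run. At -log10 q of 5 the replicated list kept 4 peaks, all in introns (2.70 times random; promoter, exon and intergenic 0) and overlapping both replicates (100% and 100%), with no TSS or gene list value. Replicated peaks overlapping replicates 1 and 2 were 90.7% and 56.2% with 50% of either peak, and 97.4% and 71.1% at -log10 p of 5.

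Location over random was 5.93 (promoter), 1.84 (exon), 1.20 (intron) and 0.464 (intergenic) with promoters to 2.5 kb. It was 4.47, 1.32 and 0.464 for promoter, intron and intergenic with TSSs of all genes, and 7.22 and 1.38 for promoter and intron by covered bases. Introns were at 1.36 at -log10 p of 5, and peaks in both replicates gave 7.22 (promoter) and 1.37 (intron). With 1 replicate left out it ranged from 6.72 to 6.95 (promoter), 2.21 to 2.43 (exon), 1.35 to 1.36 (intron) and 0.512 to 0.543 (intergenic). The TSS to flank ratio at -log10 p of 5 was 1.40 (all), 0.823 (CpG-rich) and 3.63 (CpG-poor). With 1 replicate left out it ranged from 1.05 to 1.13 (all), 0.590 to 0.660 (CpG-rich) and 2.69 to 2.90 (CpG-poor), and the X ratio from 0.0178 to 0.0364.

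Percentiles of lists whose call changed were as follows, in the replicated list unless R1 or R2 (replicate 1 or 2) is given. Windows of 20 kb gave endothelium 99.7, housekeeping 99.2, heart 97.6 (R1 75.4) and receptors 50, and 100 kb gave heart 95.1. Without peaks within 2.5 kb of a TSS, epithelium was at 49.3 (R1 90.8, R2 48.4), muscle at 49.6 (R1 97.4, R2 99.7), heart at 48.8 (R1 95.3, R2 97.2), receptors at 50 and skeleton at 99.9 (R1 97.3). Matching on promoter CpG gave epithelium 99.6 (R2 97.0), neural 91.5, muscle 96.6 and receptors 50. Window GC gave epithelium 93.3, skeleton 97.8 (R1 87.7), muscle 53.4, heart 46.3 and receptors 50. Random lists without receptors gave skeleton 99.4 (R1 96.8), muscle 96.2 and heart 98.0 (R1 96.5, R2 95.8). Peaks in both replicates gave muscle 49.7, endothelium 98.9, heart 97.0, gut, pancreas and kidney 99.3 and receptors 50. Replicate 1 at equal number gave skeleton 94.4 and endothelium 99.4. With 1 replicate left out, percentiles ranged from 96.9 to 98.7 (endothelium), 82.4 to 99.3 (Hox) and 1.51 to 75.9 (blood). Percentiles from 48.4 to 50 above mean that list and random medians were both 0, whereas with window GC they were 0.257% against 0.231% (muscle) and 0.485% against 0.524% (heart). For the replicate difference, epithelium was at 96.8 by -log10 p. All deposited peaks gave facial mesenchyme 100, Hox 100, endothelium 98.3, blood 2.25 and receptors 0, where replicate 1 has more peaks by construction. Covered shares of named genes lay beyond 1 SD in 126 of the settings with 1 replicate left out and within it in 32. The lists differ in length, with 55332 peaks in replicate 1, 18093 in replicate 2 and 17364 in the replicated list. The count therefore does not by itself measure how stable the shares are. Causes were otherwise not tested. No paired analysis was possible because there is 1 group.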

Other observations

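The 4 Hox clusters differed from one another, although they were treated as 1 list above. From its first to its last gene, the Hoxd cluster on chromosome 2 was covered at 3.60% by replicated peaks (6.60% in replicate 1, 1.69% in replicate 2). Hoxc on chromosome 15 had 1.16% (0.985% and 0.705%) and Hoxa on chromosome 6 had 0.817% (5.65% and 0.358%). Hoxb on chromosome 11 had 0.125%, with 1 replicated peak over 173.9 kb, but 1.48% in replicate 1 and 0.244% in replicate 2, so the order of the clusters below Hoxd depended on the list. These regions were chosen after the gene list values had been seen.

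Some gene bodies held long arrays of called peaks, which need not be separate marked regions. Gse1 on chromosome 8, from 120228456 to 120581390, held 112 replicated peaks covering 19.6% of the gene, with 23.7% in replicate 1 and 12.4% in replicate 2. Nfix, which encodes a nuclear factor I protein, had 36 over 100.5 kb (19.1%), and Sept9, a septin gene, had 51 (15.4%). Prdm16, a regulator of palate and brown fat development, had 55 (7.34%), and the zinc finger gene Zfp423 had 47 (6.75%). Replicated peaks were rich in G and C, with a median GC content of 54.7% against 41.7% for the genome, and with 53.8% in introns and 54.3% in intergenic sequence. The gene bodies were chosen after their values had been seen.

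The tests of the next 3 patterns were written down before their results were seen, with 1 exception that is named. The X held few peaks. Base composition and gene density can account for part of this at most. Autosomal bins of 100 kb predicted 3758 X peaks in replicate 1, and 1730 once matched on GC content and TSS number. The observed count was 0.0362 and 0.0786 of these, and 0.0786 was the highest matched ratio of the 4 lists. A lower copy number of the X in pools of both sexes, called against a genome-wide background, does not account for the whole either. At 0.75 of their enrichment, 19.1% to 39.2% of autosomal peaks would still exceed the lower edge of called enrichment (its 10th percentile), at least 10.7 times the X ratio, past the bound of 2 times set in advance. As copy number would also predict, that factor takes away most autosomal peaks, and called X peaks were about as enriched as autosomal ones (median 3.51 against 3.51 in replicate 1, 3.24 against 3.35 in replicate 2). Called peaks on every chromosome had passed a threshold, so similar medians do not tell copy number from other causes. Whether copy number acts in part stays open. The factor of 0.75 stands for equal numbers of both sexes, which the labels do not state. To reach the X ratio, a factor of at most 0.595 would be needed, or males at 81.0% to 99.9% of the tissue (worked out afterwards), whereas the labels give pools of both sexes. The X ratio used for copy number was not corrected for base composition and gene density, so the 2 explanations were each tested alone and not together. No biological explanation was tested.

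Replicate 2 held fewer peaks than replicate 1. Fewer reads in replicate 2 is a candidate explanation, which the tables leave open. At overlapping peaks the median of the enrichment ratio, replicate 2 over replicate 1, was 0.89998, at the bound of 0.9 set in advance. The median enrichment at these peaks was 3.82 in replicate 1 and 3.49 in replicate 2. The median ratio went from 1.34 among the weakest replicate 1 peaks to 0.697 among the strongest, as selection of chance highs alone could produce. Different regions in the embryo pools were not excluded either, since 77.6% of the strongest 10% of replicate 2 peaks overlapped replicate 1, short of the 80% set in advance. Replicate 2 peaks that missed replicate 1 were weaker (median enrichment 3.24 against 3.49).

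Facial mesenchyme transcription factor genes lay above matched random lists. Base composition does not account for it, since the list stayed at percentile 100 in the replicated list and both replicates with matching also on promoter CpG ratio or window GC. Promoter peaks alone do not either, since without peaks within 2.5 kb of a TSS the lowest percentile was again 100. Whether this may be a general feature of developmental transcription factor genes stays open. Against 45 transcription factor genes of the other lists, the 31 facial genes had the higher median in the replicated list (1.00% against 0.668%), replicate 1 (2.66% against 1.34%) and replicate 2 (0.881% against 0.427%), but the difference lay at percentile 94.0, 96.2 and 99.2 of 10000 random reassignments, short of the bound set in advance in the first and second.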
